A study of Mus musculus with 4 samples.

How the data were processed

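Gene expression was measured in 4 samples of sorted mouse small intestinal cells, 1 array each. Per the labels, Dclk1+ and Dclk1- cells came from the normal epithelium of Dclk1-CreERT2 mice and from intestinal tumors of Dclk1-CreERT2 mice that also carried the Apc-Min allele. The normal samples came from mice aged 26 weeks (1 mouse for Dclk1-, 2 mice pooled for Dclk1+) and the tumor samples from mice aged over 16 weeks (1 mouse of 17 weeks for Dclk1-, 7 mice pooled for Dclk1+); all mice were male. Per the labels' protocols, minced tissue was digested with collagenase and DNase, Dclk1+ tumor cells were sorted as GFP-expressing cells, total RNA was extracted from sorted cells with column kits, amplified RNA was made with an amino allyl kit, and the dye was Cy5. The gates for the other samples are not given in the sources used here.

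The scanner files hold, per the file headers, the median intensity of each spot and of its local background on a linear scale, joined from scans at several gains by straight-line fits. The unit is brightness, with nothing subtracted. Each array has 23473 probes on 23474 spots, 2736 blank spots, 144 control spots and 1102 positions without a probe. The series table that the authors deposited holds intensity values with empty cells for dim probes, and its scale is not stated in the labels. Set against the scanner values, each of its columns is a straight line of the spot intensity: a constant close to the mean of the blank spots was subtracted, and a factor put the median of the listed probes at 25. The column medians are 24.99 for Dclk1- tumor, 25.0 for Dclk1+ tumor, 25.01 for Dclk1- normal and 25.0 for Dclk1+ normal. These values are called normalised intensities here, and levels are quoted in them, because they are on a linear scale. They are not level between arrays, since each array has its own factor. With empty cells at the array's lowest value, the median log2 difference over genes listed on either array was 0.33 and 0.24 for Dclk1+ against Dclk1- in tumor and normal. It was -0.37 and -0.45 for tumor against normal in Dclk1+ and Dclk1- cells. A brighter spot has a higher value.

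The analysis started from the spot intensities. The local background was not subtracted, because it followed the spot itself (correlation of logs 0.98, 0.971, 0.924 and 0.94 in Dclk1- tumor, Dclk1+ tumor, Dclk1- normal and Dclk1+ normal). Background was corrected with normexp in limma 3.58.1 (R 4.3.3) with an offset of 50 on all spots, control spots were dropped, 3 flagged spots of Dclk1- tumor and 1 of Dclk1- normal were left out, and the 4 arrays were quantile normalized and put on the log2 scale. A spot was above background where it exceeded the mean of the array's blank spots plus 2 SD. The offset compresses differences of dim genes. Arrays were simulated with 23473 probes, the real blank spots' spread and a small assumed noise in each spot. There, 8-fold changes were called 4-fold or more in 77.3% of changed genes with a signal over 100 above the blanks. The share was 24.4% between 25 and 100, and 0% under 25. An offset of 16 gave 100%, 48.9% and 4.5%. The simulation called 0 unchanged genes, but its noise was assumed and not measured on replicates. It therefore says nothing of false calls on the real arrays.

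Probes were named from the platform table: 16631 probes have 1 symbol, 0 have several, and 6842 are unnamed here. Symbols were brought to those of the GRCm38.p6 RefSeq annotation, which was used for names only: 12622 were current, 3947 were synonyms of 1 gene, 59 were synonyms of several and 3 were unmatched, and the last 2 kinds kept the array's name. This gave 16390 genes. The array's build is not given in the sources used here, so no coordinates are printed. For the 229 genes with several probes, the probe with the highest mean over the 4 arrays was used. The SD between probes of a gene, over genes with several probes above background, was 0.39 log2 for Dclk1+ against Dclk1- in tumor, 0.79 in normal, 0.51 for tumor against normal in Dclk1+ and 0.71 in Dclk1-, and the probes of 2 genes differed 2-fold or more in opposite directions for tumor against normal in Dclk1+ cells. Symbols can be out of date: the probe named Gapdh was close to background on all 4 arrays (3.38 in Dclk1+ tumor, 5.78 in Dclk1- normal and 5.47 in Dclk1+ normal, not listed in Dclk1- tumor), so it checks nothing. Probes of close gene families can bind more than 1 member's RNA.

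The 4 comparisons were fixed before the data were examined: Dclk1+ against Dclk1- cells in tumor and in normal epithelium, and tumor against normal in Dclk1+ and in Dclk1- cells. With 1 array in each group there is no replicate, no test and no p-value, and the number of arrays limits the precision; a difference here compares 2 arrays, not the conditions in general. Sizes are log2 differences, counts are of genes at least 4-fold apart that are above background on at least 1 of the 2 arrays, and a gene above background on only 1 of them is given as at least N-fold, against the higher of the array's lowest signal above background and the dim probe's own. Members of 29 gene lists (614 genes), also fixed beforehand, were summarised by their median over the members above background, with a 95% order-statistic interval over members and a percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A percentile describes these arrays and is not a test of the conditions. On simulated differences over 16390 genes, 4.0% of 100 unchanged lists fell outside the percentiles 2.5 to 97.5, and 100% of lists shifted by 0.5 lay above. Lists overlap: 10 tuft identity genes and 10 intestinal stem cell genes are also in another list. Genes are named by a fixed rule: the 8 highest and 8 lowest differences among genes above background on both arrays, the 4 brightest genes in each direction above background on 1 array only, up to 4 members of each described list with the largest differences, any member of the tuft identity, stem cell and Wnt target lists, and Dclk1, Il17rb, Lgr5, Apc, housekeeping and sex-linked genes as checks of the labels.

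Alternatives were plain subtraction with a floor, no background correction, an offset of 16, median, 75th percentile and cyclic loess scaling, quantile normalization within a histology, no filter or both arrays above background, the authors' values, the mean over a gene's probes, and thresholds of 2-fold and 8-fold. Subtracting the local background before normexp was added after the data were examined. Simulations and statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Tumor and normal arrays also differ technically: over bright spots the local background reached 59.8% of the spot intensity on Dclk1- tumor and 48.4% on Dclk1+ tumor, against 26.8% and 25.2% on Dclk1- and Dclk1+ normal. Each histology lies in its own pair of arrays, and the ages given for tumor (17 weeks, or over 16) and normal samples (26 weeks) differ, so array set, age and histology cannot be told apart in tumor against normal comparisons. Dclk1+ against Dclk1- comparisons stay within a pair, but the animals differ with the sort there (1 mouse against 7 pooled in tumor, 1 against 2 pooled in normal). The arrays of a pair also differ technically. The median of the positive control spots was 4343 in Dclk1- and 2556 in Dclk1+ tumor, and 3983 in Dclk1- and 1016 in Dclk1+ normal.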

Results

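The series asks how Dclk1+ cells of the small intestine differ from their Dclk1- neighbours, in normal mucosa and in tumors of mice with the Apc-Min allele, which loses Apc function and starts Wnt-driven adenomas. Dclk1, a doublecortin-like kinase, marks tuft cells, rare chemosensory cells of the gut epithelium. The data are 4 arrays with 1 array in each group: Dclk1- tumor, Dclk1+ tumor, Dclk1- normal and Dclk1+ normal. Between 63.3% (Dclk1- tumor) and 70.9% (Dclk1+ normal) of the 23473 probes were above background, which left 10919, 11568, 11710 and 12075 of 16390 genes in Dclk1- tumor, Dclk1+ tumor, Dclk1- normal and Dclk1+ normal. There were no replicates, so no difference below could be set against a spread between animals, and each is a difference between 2 arrays.

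The sorting gene was checked first. The normalised intensity of Dclk1 was 9.49 in Dclk1- tumor, 61.8 in Dclk1+ tumor, 179.8 in Dclk1- normal and 736 in Dclk1+ normal, so that the Dclk1+ sample was the brighter of each pair, 6.50-fold in tumor and 4.09-fold in normal. The log2 differences used below, whose offset compresses dim signals such as these, were 0.69 in tumor and 1.41 in normal. The Dclk1- normal sample was still brighter than the Dclk1+ tumor sample. Apc was dim on all 4 arrays, between 6.84 and 12.5, and its probe does not tell the Min allele from the wild type. The Y-linked Kdm5d was above background on all 4 arrays (7.2 to 15.9), and the labels give all mice as male. Actb, a cytoskeletal reference gene, ranged from 22919 to 34265.

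In tumors, Dclk1+ cells had far higher signals than Dclk1- cells for the tuft cell programme. Lrmp led with a log2 difference of 5.88 (normalised intensity 4518 against 8.09), followed by Alox5ap, which presents arachidonic acid to 5-lipoxygenase (5.60; 7625 against 75.5), and by Trpm5, the cation channel of taste-type signalling (4.87; 2343 against 14.8). The Dclk1- tumor sample had higher signals for Krt20, a keratin of mature epithelium (-3.72; 463 against 5699), and for Apoa4, an apolipoprotein of enterocytes (-3.54; 28.3 against 847). Il17rb, the receptor chain for IL-25, stood at 286 in Dclk1+ cells and was not above background in Dclk1- cells, which makes it at least 4.79-fold higher.

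Of the 34 tuft identity genes above background in this pair, 17 were at least 2-fold higher and 0 were 2-fold lower in Dclk1+ tumor cells, with a median of 1.22 (interval 0.68 to 2.34, percentile 99.8), and 1.18 with genes below background on 1 array held at their bound. Fyb (4.34), the transcription factor Gfi1b (3.35), the small GTPase Rac2 (2.88), Ltc4s, the leukotriene C4 synthase (2.86), Skap2 (2.53) and Ptgs1, a cyclooxygenase (2.19), were among them. Rgs13, a regulator of G-protein signalling, was at least 10.8-fold higher (696 in Dclk1+ cells). Taste-type signalling genes followed, with Gng13 (4.86) and Plcb2 (3.97) beside Trpm5, 4 of 16 genes 2-fold higher and 0 lower, and a list median of 0.25 (percentile 99.6). In eicosanoid synthesis 4 of 14 genes were 2-fold higher and 0 lower, with a median of 0.09 (percentile 94.7). The IL-25, IL-13 and IL-4 list had a median of 0.10 with 2 of 19 higher and 1 lower, among them Tslp at 1.60 and Il4ra at -1.15. Outside the lists, Tm4sf4 (4.23; 11862 against 456) and the inositol phosphatase Inpp5j (3.85; 2423 against 100.2) were also high in Dclk1+ cells, and Hmx2, a homeobox gene, was at least 20.1-fold higher (1353).

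Lower signals in Dclk1+ tumor cells lay in differentiated epithelium. Of 27 enterocyte genes 12 were at least 2-fold lower and 0 higher (median -0.56, percentile 0), with Mep1b, a brush border protease, at -2.45 and Fabp2, a fatty acid binding protein, at -2.26. Goblet genes had a median of -0.43 with 5 of 15 lower and 0 higher, led by Zg16 (-2.71; 1632 against 9847) and Tff3 (-1.98), and Paneth genes had a median of -0.44 with 3 of 7 lower and 0 higher, led by the defensin Defa5 (-2.32). The distal small intestine list had a median of -2.12 (7 of 10 lower), with Slc51b, a bile acid exporter subunit (-2.93), Muc3 (-2.67) and Fabp6, the ileal bile acid binding protein (-2.36), and the proximal list a median of 0.00 (interval -2.62 to 0.93) with 2 of 10 lower and 0 higher. Epithelial genes had a median of -0.00 with 2 of 20 lower and 1 higher. Enteroendocrine genes had a median of -0.09 with 2 of 16 lower and 1 higher: Sct, which encodes secretin, was at 2.67 (908 against 80.8) and Gip at -1.48. The MHC class II gene H2-Aa was at -2.70 and the cell cycle list at a median of -0.19 (percentile 0.06), where Birc5 was at -1.14. Myeloid genes also sat on the Dclk1- side, with a median of -0.25 over 20 genes (percentile 0), Il1b at -1.83, the complement genes C1qa at -1.71 and C1qb at -1.43, and so did secreted inflammatory genes (median -0.19), with Cxcl2 at -1.70 and Saa3 at -1.60. Fetal and regenerative epithelium genes (median -0.17, 4 of 12 lower) held Ly6d at -1.59. Fibroblast and smooth muscle genes had a median of -0.10 (percentile 0.61), and immediate-early and dissociation genes of -0.11 (percentile 1.7). For other cell types the median was 0.04 for T and NK cells, 0.08 for B and plasma cells and 0.00 for mast cells and basophils. It was -0.01 for endothelium, 0.12 for neural and glial and 0.08 for erythroid genes.

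On the log2 scale, whose offset compresses dim signals, stem cell and Wnt target genes were close to level between the tumor samples. A change of 2-fold or more in a dim member can be missed there. The intestinal stem cell list had a median of 0.02 with 0 of 21 genes 2-fold higher or lower, and the Wnt target list a median of -0.00 with 0 of 23 higher and 1 lower, Wif1. Lgr5, the receptor that marks crypt base stem cells, stood at 59.1 in Dclk1+ and 60.3 in Dclk1- tumor cells. Ascl2 (0.79), Hopx (0.86) and Msi1 (0.70) were brighter in Dclk1+ cells, while other stem cell genes were dimmer (interval of the list median -0.09 to 0.26). Wif1, a secreted Wnt inhibitor, was dimmer too (-1.87, with 209 against 743).

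In all, 53 genes were at least 4-fold higher and 35 at least 4-fold lower in Dclk1+ than in Dclk1- tumor cells among 12201 genes. The authors' values gave 530 and 417, and plain subtraction 334 and 456, with more lower than higher genes, as did a 2-fold threshold (214 and 260). With the local background subtracted, an alternative added later, the tuft median was 0.68, and Apoa4 (0.16), Wif1 (0.70) and Birc5 (2.51) were on the Dclk1+ side.

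**Figure D1:**
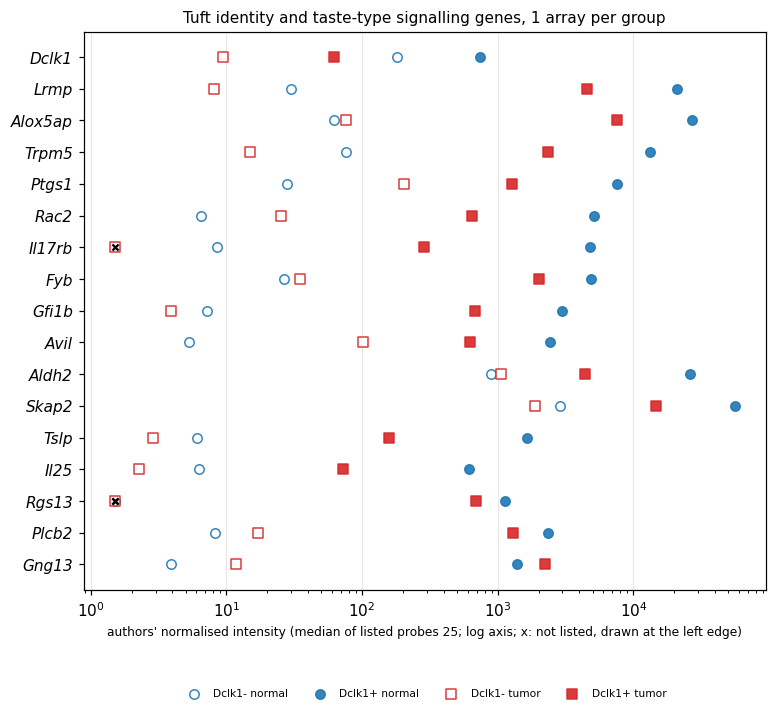
Normalised intensity (log axis) of tuft identity and taste-type signalling genes in the 4 samples, 1 point per array, with a cross at the left edge where the authors list no value. Dclk1+ samples (filled) lie above Dclk1- samples (open) of the same histology for each gene drawn, and Dclk1+ normal lies above Dclk1+ tumor for all of them but Gng13 (1386 against 2226).

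In normal epithelium the same comparison showed larger differences. Lrmp and Alox5ap were both higher in Dclk1+ cells by a log2 difference of 7.34 (21104 against 29.9, and 27148 against 62.1), and Hap1 (6.61), Trpm5 (6.21), Ptgs1 (5.95), Mcub (5.74), Rac2 (5.72) and Il17rb (5.58; 4810 against 8.59) completed the 8 highest. The Dclk1- side was led by hormone, goblet and enterocyte genes: Nts, which encodes neurotensin (-6.95; 8.42 against 8765), the goblet gene Clca1 (-6.76), adenosine deaminase Ada (-6.65), cholecystokinin Cck (-6.54) and Agr2, a disulfide isomerase of secretory cells (-6.06; 72.8 against 8436).

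Tuft identity genes had a median of 2.50 over 38 genes (interval 1.41 to 3.84, percentile 99.9), with 27 at least 2-fold higher and 0 lower. Among them were Aldh2 (4.36), Avil (4.67), Tslp (4.11), which encodes an alarmin cytokine, and Il25 (2.96; 618 against 6.31). Rgs13 was at least 13.3-fold higher, and outside the list Dnah6 was at least 30.8-fold and Kcnmb4 at least 26.3-fold higher. Taste-type signalling genes had a median of 0.59 with 7 of 15 higher and 1 lower, and eicosanoid synthesis genes a median of 0.39 with 5 of 13 higher and 0 lower. Interferon-stimulated genes had a median of 0.27 over 17 genes (percentile 99.4), with Oas2 (4.25), Bst2 (2.69), Oas1a (2.16) and Rsad2 (1.67) higher and 1 lower.

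On the Dclk1- side of normal epithelium, 19 of 30 enterocyte genes were at least 2-fold lower in Dclk1+ cells and 1 higher (median -1.71), as were 9 of 16 goblet genes (median -1.47), 5 of 7 Paneth genes (median -1.31) and 10 of 22 enteroendocrine genes (median -0.67). Examples were Apoa4 (-5.20), Zg16 (-5.40), Spink4 (-5.36), Itln1 (-4.44) and Gip (-5.50), and Pyy, peptide YY, was at least 31.2-fold lower. Krt20 was at -6.03, and Fabp1 was the higher enterocyte gene (1.60; 63956 against 14387). Epithelial genes had a median of -0.34 with 4 of 20 lower and 1 higher. Cell cycle genes had a median of -0.36 with 11 of 31 lower, led by Birc5 (-3.63), Cdc20 (-2.65) and Cdk1 (-2.30). Of the 3 MHC class II genes above background, H2-Aa was at -3.77 and Cd74 at -2.83. The distal list had a median of -3.31 with 7 of 11 lower and 0 higher, and the proximal list of -0.40 with 4 of 9 lower and 1 higher. The stem cell list had a median of -0.06, where Hopx was at 3.18 and Ephb3 at -2.62, and the Wnt target list had a median of -0.00, where Ccnd2 was at -2.89 and Mmp7 at -2.57. Immediate-early and dissociation genes had a median of -0.24 with 3 of 21 lower, among them Egr1 at -2.99 and Jun at -2.53, and 1 higher. Among markers of other cell types, myeloid genes had a median of 0.15 (interval 0.01 to 0.50) with 2 of 15 higher, Il1b (1.63) and C1qb (1.32), and 0 lower, and mast cell and basophil genes a median of 0.13 with 1 of 5 higher, Mcpt2 (1.19), and 0 lower. The median was -0.03 for T and NK cells, 0.02 for B and plasma cells, 0.03 for fibroblast and smooth muscle, 0.05 for endothelium, 0.06 for neural and glial and 0.04 for erythroid genes.

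In normal epithelium 206 genes were at least 4-fold higher and 277 at least 4-fold lower in Dclk1+ cells, among 12846 genes. The authors' values gave 956 and 922, with more higher than lower genes, and plain subtraction 688 and 934.

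The Dclk1+ minus Dclk1- differences of tumor and normal epithelium share no array. Across 13467 genes, which are not independent replicates, they had Pearson's r of 0.61 and Spearman's rho of 0.41, against r of 0.361 and rho of 0.233 with the local background subtracted. Of the 53 genes 4-fold higher in tumor, 47 were also 4-fold higher in normal, against 0.81 for independent lists, and of the 35 lower in tumor 29 were also lower in normal, against 0.72. Dim genes are rarely called 4-fold, so both lists draw mainly on brighter genes, and the numbers for independent lists are likely too low. For 265 genes the differences themselves differed 4-fold or more, 183 towards a more positive and 82 towards a more negative difference in tumor, against 1551 genes with plain subtraction and 1884 with the authors' values. Nts, Agr2, Cck and Clca1 stood on the positive side: Agr2 was at -0.04 in tumor against -6.06 in normal, with 10404 in Dclk1+ and 8875 in Dclk1- tumor cells. On the negative side stood Ifitm1 (-0.41 against 3.80), Ptgs1 (2.19 against 5.95) and Il17rb. None of these differences between histologies could be tested.

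**Figure D2:**
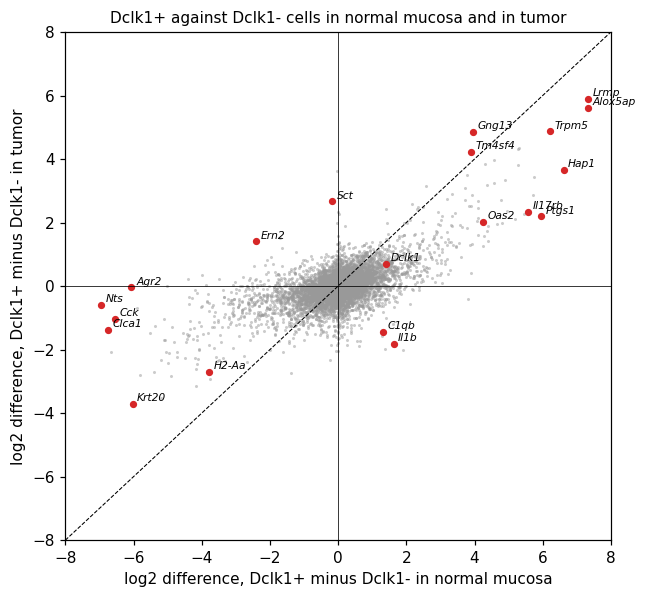
Log2 difference between Dclk1+ and Dclk1- cells in tumor (vertical) against that in normal mucosa (horizontal), 1 grey point per gene above background on at least 1 array, named genes in red, with a dashed line of equality. Lrmp and Alox5ap lie high on both axes, Agr2 and Nts are far below 0 in normal (-6.06 and -6.95) and near 0 in tumor (-0.04 and -0.58), and Il1b and C1qb have opposite signs.

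Set against the Dclk1+ normal sample, the Dclk1+ tumor sample had much higher signals for Wfdc18 (8.20; 29114 against 20.8), the chaperone clusterin, Clu (7.11; 14492 against 35.4), the gastric peptides Tff2 (7.06) and Gkn3 (6.77), the matrix protease Mmp7 (6.60), Agr2 (6.22), Ern2 (5.77) and the claudin Cldn2 (5.73). Tuft genes were lower in tumor, led by Il17rb (-3.40; 286 against 4810), and outside the list so were Cst6 (-3.21), Bcl2l14 (-2.85), Hap1 (-2.68) and the cell cycle inhibitor Cdkn1c (-2.67).

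Of 38 tuft identity genes 22 were at least 2-fold lower and 0 higher in tumor (median -1.29, interval -1.56 to -0.68, percentile 0). Tslp was at -2.55, Rac2 at -2.44, Dclk1 at -2.36, Ptgs1 at -2.09, Trpm5 at -2.06 and Il25 at -2.04, while Fyb was at -0.75 and Rgs13 at -0.28. Of 17 taste-type signalling genes 2 were higher and 2 lower, with Gnat3 at -1.92 and Gng13 at 1.11, and eicosanoid synthesis genes had a median of -0.28 with 3 of 13 lower. Interferon-stimulated genes had a median of -0.53 with 6 of 16 lower, led by Rsad2 (-2.64) and Oas2 (-2.55). Epithelial genes had a median of -0.95 with 9 of 20 lower and 1 higher; lower were the actin bundler Vil1 (-1.92) and Gpa33 (-1.58).

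Wnt targets stood on the tumor side, with 7 of 24 at least 2-fold higher and 0 lower (median 0.27, percentile 100): Mmp7, Ccnd2 (3.94), Nkd1, an inhibitor of Wnt signalling (3.16), Notum (1.40) and Tnfrsf19 (1.27), with Wif1 at least 3.77-fold higher. The stem cell list, which shares members with the Wnt target list, had a median of 0.01 (percentile 74.6) with 3 of 22 higher and 1 lower. In it Slc12a2 (1.67) and Ascl2 (1.22) were higher and Hopx (-1.07) lower, and Lgr5 stood at 59.1 against 26.4. Paneth genes had a median of 2.74 with 5 of 7 higher, including Defa5 (3.91) and Itln1 (3.63). If 18.1% of the Dclk1+ tumor sample were Dclk1- tumor cells, these would give 77.8% of its Defa5 signal. Goblet genes had a median of 0.30 with 5 of 16 higher, including Spink4 (4.48) and Spdef (2.36), and Retnlb at least 12.5-fold. Of 26 enterocyte genes 3 were higher and 3 lower (median -0.07), with Reg1 at 2.78, Prap1 at 2.59 and Fabp1 at -1.71. Cell cycle genes were higher, 9 of 29 by 2-fold or more and 0 lower (median 0.63, percentile 100), with Cdc20 at 1.97 and Birc5 at 1.75. Fetal and regenerative epithelium genes had a median of 0.48 with 5 of 11 higher and 0 lower, among them S100a6 at 4.94 and Anxa3 at 2.52. The alarmin Il33 was at 3.95 (1071 against 8.52) and Lcn2, a secreted iron-binding defence protein, at 3.66. Arg1 and Timp1 were at least 9.76-fold and 9.9-fold higher.

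Between Dclk1+ tumor and normal cells 150 genes were at least 4-fold higher and 54 lower among 12870, so 73.5% were higher, against 61.3% with median scaling (130 and 82), 58.6% with 75th percentile scaling (130 and 92) and 47.2% with the authors' values (767 and 857). Tumor and normal arrays differ in local background and the samples in the age given, so array set, age and histology cannot be told apart, and subtracting the background gave 46.6% (104 and 119) and put Reg1 at -1.12.

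**Figure D3:**
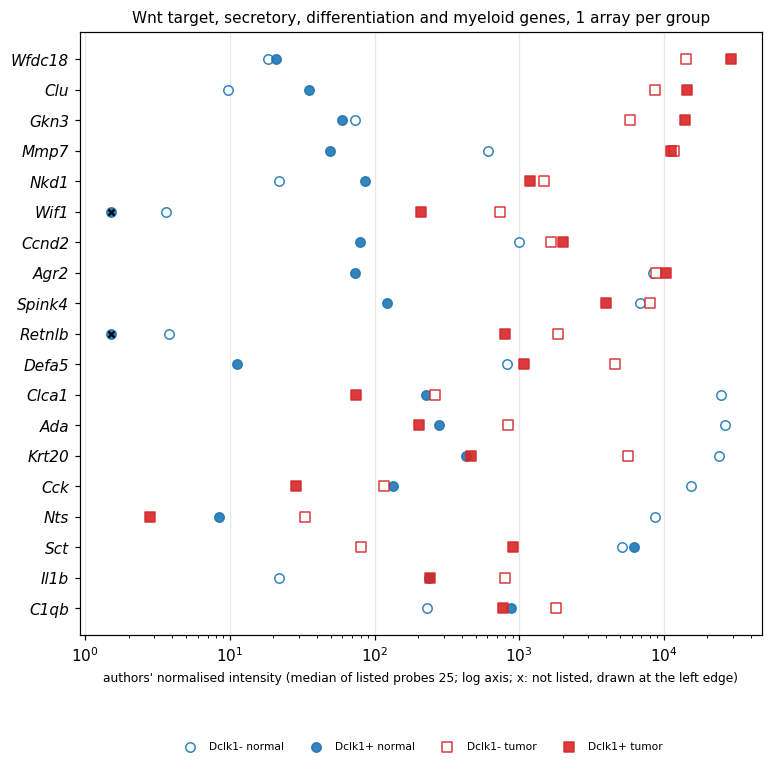
Normalised intensity (log axis) of Wnt target, secretory, differentiation and myeloid genes in the 4 samples, 1 point per array, with a cross at the left edge where the authors list no value. Both tumor samples (red) lie far above both normal samples (blue) for Wfdc18, Clu and Gkn3, Agr2 is low only in Dclk1+ normal cells (72.8), and Nts is high only in Dclk1- normal cells (8765).

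Between Dclk1- tumor and Dclk1- normal cells, Wfdc18 (7.68), Clu (7.04) and Gkn3 (5.65) were again among the highest, with the interferon-induced membrane protein Ifitm1 (7.02; 8388 against 8.75), arginase Arg1 (5.41) and Retnlb (5.05). The lowest were the hormone genes Cck (-6.46; 115 against 15348), Nts (-6.45) and Sct (-5.10), the goblet gene Clca1 (-6.29), Sec14l2 (-5.19) and Ada (-4.80).

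Wnt targets had a median of 0.39 with 8 of 24 at least 2-fold higher and 2 lower (percentile 100): Mmp7 (4.47), Nkd1 (4.43), Wif1 (3.76) and Notum (1.64) were higher, and Ephb3 (-2.60) and Ephb2 (-1.60) lower. The stem cell list had a median of 0.09 (percentile 93.5) with 3 of 22 higher and 3 lower. Lgr5 was at least 1.91-fold higher (60.3 in tumor). Differentiation genes were lower: 14 of 30 enterocyte genes (median -0.92), with Apoc3 at -4.10 and the amino acid transporter Slc6a19 at -2.94, and 11 of 23 enteroendocrine genes (median -0.72). Epithelial genes had a median of -1.25 with 13 of 20 lower, including Cldn15 (-3.53) and Vil1 (-2.64), and 1 higher. Of 16 goblet genes 7 were at least 2-fold lower and 1, Retnlb, higher (median -0.19), and of 7 Paneth genes 3 were higher and 0 lower (median 0.70), with Mmp7 and Defa5 (2.74). The 3 MHC class II genes had a median of -2.31, with H2-Aa at -2.62 and Cd74 at -2.31, and B2m, the light chain of MHC class I, stood at 2759 against 19988. Interferon-stimulated genes had a median of -0.21, with Oas1a at -2.53, Stat2 at -2.29 and Rsad2 at -2.17. Cell cycle genes had a median of 0.14 with 1 of 32 higher and 0 lower. The tuft identity list had a median of -0.03 with 2 of 29 higher and 1 lower, where Ptgs1 was at 1.67 and Dclk1 at -1.64.

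Of 20 myeloid genes 6 were at least 2-fold higher and 0 lower in Dclk1- tumor cells (median 0.45, interval 0.21 to 1.00, percentile 100), with Il1b at 3.57, C1qb at 2.94, C1qa at 2.22 and S100a8 at 2.04. Secreted inflammatory genes had a median of 0.13, with Lcn2 at 4.49, Cxcl2 at 2.70 and Saa3 at 2.14. Fibroblast and smooth muscle genes had a median of 0.20 with Vim at 2.50, and endothelial genes of 0.10 with Flt1 at 1.83, whereas the median was -0.09 for T and NK cells and 0.02 for B and plasma cells. In this pair 144 genes were at least 4-fold higher and 161 lower among 12343, the authors' values gave 694 and 1073, and with the local background subtracted Wif1 was at -0.06. More genes were higher than lower with plain subtraction (792 and 636), an offset of 16 (271 and 262), no background correction (243 and 242) and a 2-fold threshold (718 and 647). Of the 150 genes higher in Dclk1+ tumor cells 57 were also higher in Dclk1- tumor cells, against 1.6 for independent lists, and of the 54 lower 10 were also lower, against 0.65. Here too the numbers for independent lists are likely too low, because dim genes are rarely called 4-fold.

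**Figure D4:**
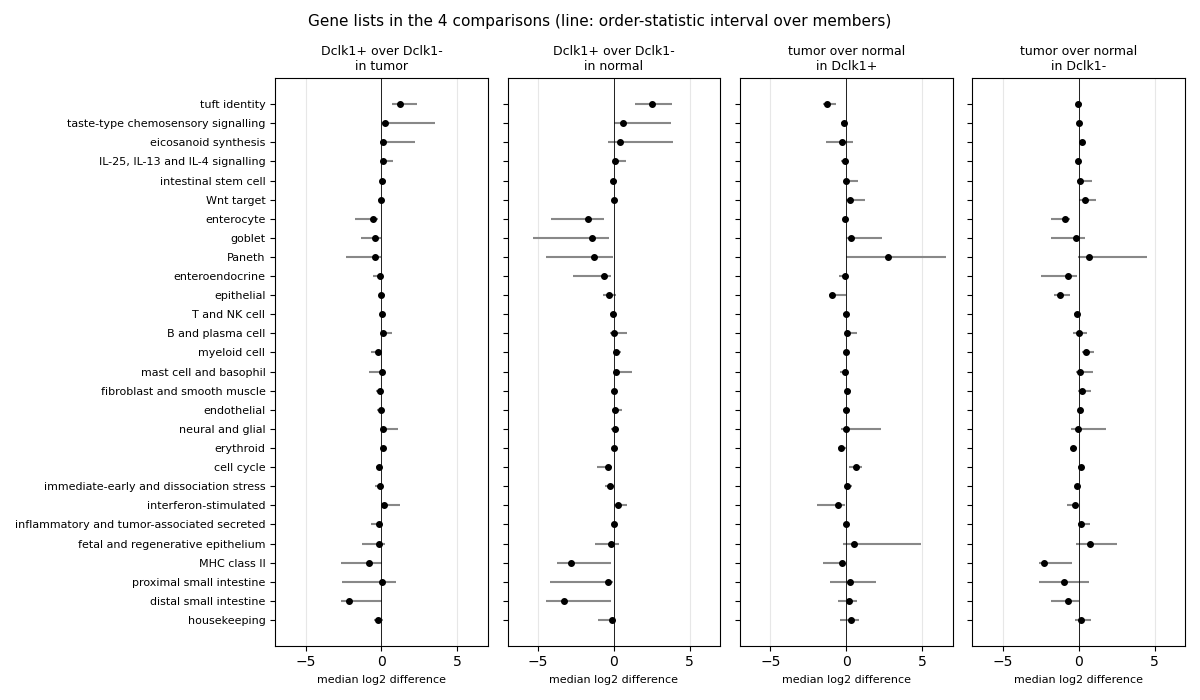
Median log2 difference of each gene list (point) with its 95% order-statistic interval over members (line; the range, with lower coverage, under 6 members) in the 4 comparisons, for members above background on at least 1 of the 2 arrays. The tuft identity list lies at 1.22 and 2.50 for Dclk1+ against Dclk1- cells and at -1.29 for tumor against normal in Dclk1+ cells.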

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

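All tests weighed in this part were chosen only after the result they measure was seen. The opposite directions given here were picked out because a gene was at least 2-fold higher in 1 pair of samples and at least 2-fold lower in the matching pair. With 1 array per group, these opposite-direction differences were not tested.

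Between Dclk1+ and Dclk1- cells, 3 named genes had opposite signs in tumor and in normal epithelium. The complement gene C1qb was at -1.43 in tumor and 1.32 in normal (difference -2.75), Il1b at -1.83 and 1.63 (difference -3.46), and Ern2 at 1.41 and -2.41 (difference 3.82). Between tumor and normal, 8 named genes had opposite signs in Dclk1+ and in Dclk1- cells. Lower in Dclk1+ and higher in Dclk1- tumor cells were Ptgs1 (-2.09 and 1.67, difference -3.76), Avil (-1.42 and 1.30, difference -2.72), Hopx (-1.07 and 1.26, difference -2.33) and Mcub (-1.04 and 1.27, difference -2.31). Higher in Dclk1+ and lower in Dclk1- tumor cells were Pyy (at least 2.15 and -2.82, difference at least 4.97, since it is not above background in Dclk1+ normal cells, where its dim reading gives 2.21 and 5.03), Cpe (1.08 and -1.71, difference 2.80), Egr1 (1.42 and -1.35, difference 2.77) and Trpm4 (1.27 and -1.31, difference 2.58).

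The 6842 probes without a symbol stand outside the comparisons, and some of them differed 4-fold or more. For Dclk1+ against Dclk1- cells there were 34 in tumor (16 higher, 18 lower) and 134 in normal (52 higher, 82 lower). For tumor against normal there were 70 in Dclk1+ cells (53 higher, 17 lower) and 91 in Dclk1- cells (47 higher, 44 lower).

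Tuft identity genes were lower in Dclk1+ tumor than in Dclk1+ normal cells. Over 32 expressed members the log2 ratio of the normalised intensities had a median of -2.07 (-4.07 to 0.11). For this, dilution would need a share of 76.1% (68.2 to 83.2) of cells without tuft transcripts. Expressed meant at least 25 in Dclk1+ normal cells and at least 4-fold above Dclk1- normal cells. That choice favours low ratios, and the median gene was itself at -0.37 in these values, so the share needed may be overstated. Without the choice, all 38 members had a median of -1.99 in the same values, with empty cells at the array's lowest value. On the log2 scale, whose offset compresses dim signals, it was -1.29. The 720 genes bright in Dclk1- tumor cells allow a share of 18.1% of those cells. The gap argues against Dclk1- tumor cells, in the mix sampled, as the whole cause. Dilution by other cells would lower all members by 1 factor, but their SD of 0.955 (0.766 to 1.27) against an SD between probes of 1 gene of 0.919 (0.765 to 1.15, 40 genes) left it open. An effect of the array set alone would shift a member alike in Dclk1+ and Dclk1- cells, so that the difference of the 2 shifts is near 0. Over the 5 members bright on all 4 arrays, the shift in Dclk1+ minus the shift in Dclk1- cells had a median of -2.11 (-5.45 to -1.30). That is away from 0, but 5 members are too few to decide. Array set may still contribute, and it cannot be told apart from histology. The histology in the design, and the age given, which differs with it, stay open and untested.

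Some goblet and Paneth genes were at least 2-fold higher in Dclk1+ tumor than in Dclk1+ normal cells: 5 of 16 goblet genes (median 0.30, -0.04 to 2.36) and 5 of 7 Paneth genes (median 2.74, -0.01 to 6.60), so 10 in all, with 0 lower. Dclk1- tumor cells carried over at the same allowed share of 18.1%, read at percentile 1 of the ratios, would give a median of 25.1% of the level of the 10 genes (interval of the median 15.4 to 44.5, single genes from 9.003 to 77.8). Taking genes for a higher Dclk1+ tumor signal favours low values here. For cells carried over in the mix sampled, the median argues against carry-over as the whole cause for these 10 as a group. It leaves carry-over open for Defa5, at 77.8%. Percentile 1 is not an upper limit, though: bright genes below it, such as Krt20, allow a lower share, so the 77.8% may be overstated. Carry-over of only a subset of the Dclk1- tumor cells was not tested. For goblet cells as they are in normal mucosa, a first test counted the bright goblet genes not higher in tumor: 1 of 5 on the log2 scale (Clca1) and 3 of 5 in the normalised intensities (also Tff3, 4644 against 5037, and Zg16, 1632 against 2098), with 2 of 5 (Agr2 and Spink4) 2-fold higher, so it turned on the scale and decided nothing. A second test was devised after that outcome. It put Tff3, Clca1 and Zg16 at a median of 3.61% (0.51 to 12.6) of the level that a share of 58.6% would bring. These genes were taken for not being 2-fold higher, which alone holds them under 27.3% of that level. The 5 were chosen by brightness in Dclk1- normal cells, though, and such goblet cells would bring all 5 in proportion. Agr2 and Spink4 reached 10404 and 3993 in Dclk1+ tumor cells against 8436 and 6814 in Dclk1- normal cells. Tff3, Clca1 and Zg16 reached 4644, 74.5 and 1632 against 63010, 24890 and 77094. This argues against goblet cells as they are in normal mucosa as the whole source of Agr2 and Spink4. Goblet cells in the sort that differ from those of normal mucosa, the histology and the age stay open.

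Myeloid genes were higher in Dclk1- tumor than in Dclk1- normal cells. A lower share of epithelial cells alone, with no change among the other types, would raise the markers of every other cell type alike. Fibroblast and smooth muscle genes (0.20, -0.02 to 0.81, percentile 99.6) and endothelial genes (0.10, -0.08 to 0.27, percentile 98.5) were on that side. T and NK cell genes had a median of -0.0896 (-0.33 to 0.01, 16 genes), with an interval below the myeloid one. Their median was -0.04 with genes below background on 1 array held at their bound. Dim genes are compressed, but the T and NK cell list's percentile of 1.74 is among lists matched on signal. The T and NK cell values argue against such a lower share as the whole cause, provided that these cells did not fall along with the epithelial cells. A lower share of epithelial cells together with fewer T and NK cells was not tested. Myeloid cells in the Dclk1- tumor sample remain a candidate source. The list median of 0.45 (0.21 to 1.00, 20 genes) is the pattern itself, so it does not test this. The list's brightest members in that sample were C1qb (1813), Il1b (805) and C1qa (569), against 230.0, 21.9 and 95.3 in Dclk1- normal cells. Of the list, 1 gene is also in another list, the gate for Dclk1- cells is not given in the sources used here, and array set, age and myeloid transcripts in the tumor cells themselves were not tested.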

How the results depend on the processing

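Subtracting the local background before normexp was chosen after the data were examined, and the other alternatives before. No alternative has a test, because there is 1 array per group, and no paired analysis was possible for the same reason. Of 126 counts 58 moved by more than 1.5 times. These include every count at the 2-fold and 8-fold thresholds, which change with the cut-off itself. Of 48 tuft list medians 9 moved and 0 reversed. For the other lists 107 of 970 medians moved and 1 reversed, and for single genes 985 of 6468 values moved and 10 reversed. A list median counts as moved outside its 95% interval over members, a gene where it differs by more than the SD between probes of a gene, and the correlation outside its 95% interval over genes. Reversed counts a list only where its percentile lay outside 2.5 to 97.5, and a gene only where it differed 2-fold or more, in the analysis as reported. Smaller values took the other sign in 67 of the 970 other list medians, 2 of the 48 tuft list medians and 144 of the 6468 single gene values. Tuft medians ranged over the settings from 1.64 to 5.80 for Dclk1+ against Dclk1- in normal, 0.68 to 3.80 in tumor, -1.99 to -0.74 for tumor against normal in Dclk1+ and -0.46 to 0.03 in Dclk1- cells, where the sign was not kept. The median of all genes stood at 0.13 in both Dclk1+ against Dclk1- comparisons with median scaling, at 0.17 and 0.16 with 75th percentile scaling, and at -0.12 and -0.10 for tumor against normal in Dclk1+ and Dclk1- cells with the authors' values. Signal over background sets what can be called, and the self-test shows that dim genes are rarely called 4-fold. Where a cause is not named below, the cause was not tested.

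The values that moved are given as genes higher and lower, in the order Dclk1+ against Dclk1- in tumor, the same in normal, tumor against normal in Dclk1+, and the same in Dclk1- cells, then the genes whose differences differ 4-fold and the correlation of the differences. Plain subtraction gave 334 and 456 (tuft median 3.30), 688 and 934 (5.45), 778 and 447 (-1.71), 792 and 636 (-0.31), 1551 and 0.488. The authors' values gave 530 and 417 (3.80), 956 and 922 (5.80), 767 and 857 (-1.99), 694 and 1073 (-0.46), 1884 and 0.459. No background correction gave 81 and 66, 249 and 103 in Dclk1+ and 243 and 242 in Dclk1- tumor against normal, 452 and 0.585. An offset of 16 gave 83 and 76, 329 and 424, 266 and 112, 271 and 262, 494 and 0.579. With a threshold of 2-fold, which admits smaller differences, there were 214 and 260, 726 and 760, 550 and 539, 718 and 647, and 1187. With 8-fold, which admits fewer, there were 19 and 3, 79 and 118, 54 and 2, 29 and 36, and 53. Median scaling gave 82 lower genes for tumor against normal in Dclk1+ cells and 75th percentile scaling 92, and the correlation was 0.601 in both. Subtracting the local background gave 98 and 64 with a tuft median of 0.68 for Dclk1+ against Dclk1- in tumor, 178 lower in normal, 119 lower for tumor against normal in Dclk1+ cells, and a correlation of 0.361.

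The values that reversed by this criterion follow. With 75th percentile scaling the fibroblast and smooth muscle list had a median of 0.0307 for Dclk1+ against Dclk1- in tumor, where this scaling puts the median of the genes kept at 0.13, so the list still lay below it. With the local background subtracted, Apoa4 was at 0.16, Slc28a2 at 0.99, Wif1 at 0.70 and Birc5 at 2.51 in that comparison, Reg1 at -1.12, Onecut2 at -0.82 and Rpl13a at -0.87 for tumor against normal in Dclk1+ cells, and Wif1 at -0.0561, Uchl1 at -0.22 and Mcm4 at -0.34 in Dclk1- cells.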

Other observations

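No test of a hypothesis belongs to this part, which gives values only. Oas1a, Rsad2 and Oas2, 3 interferon-stimulated genes picked after their values were seen, were brighter in Dclk1+ than in Dclk1- cells of both histologies and dimmer in tumor than in normal samples of both kinds. Oas1a, an antiviral oligoadenylate synthetase, had a normalised intensity of 231 in Dclk1- tumor, 1861 in Dclk1+ tumor, 1845 in Dclk1- normal and 10718 in Dclk1+ normal cells. Rsad2, an antiviral enzyme, stood at 64.1, 263, 567 and 2650.0 in the same order, and Oas2 at 19.1, 308, 46.2 and 2838. Over the list the medians were 0.16 and 0.27 for Dclk1+ against Dclk1- in tumor and normal, and -0.53 and -0.21 for tumor against normal in Dclk1+ and Dclk1- cells. The antigen presentation genes B2m and H2-Aa were dimmer in tumor: B2m stood at 2759 and 3189.6 in Dclk1- and Dclk1+ tumor against 19988 and 13117 in normal, and H2-Aa at 2238 and 380.1 against 15335 and 1593.

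Single genes of epithelial signalling stood apart as well. Sct, which encodes secretin, was at 80.8 in Dclk1- tumor against 908, 5113 and 6275 in Dclk1+ tumor, Dclk1- normal and Dclk1+ normal cells. The alarmin Il33 was at 8.52 in Dclk1+ normal cells against 956, 1071 and 279.6 in Dclk1- tumor, Dclk1+ tumor and Dclk1- normal cells. Il13ra2, a receptor for IL-13, was brightest in Dclk1+ tumor cells (1189). Tff2, a gastric peptide, was at 9925 in Dclk1+ and 581 in Dclk1- tumor cells, against 3.77 and 5.46 in the normal samples.

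Housekeeping genes had list medians of -0.23 and -0.14 for Dclk1+ against Dclk1- in tumor and normal, and of 0.29 and 0.15 for tumor against normal in Dclk1+ and Dclk1- cells, with the opposite sign with the local background subtracted in the 1st, 3rd and 4th (0.03, -0.03 and -0.02). The authors' values gave 0.21 in the 1st and -0.08 in the 3rd, where the median of the genes kept was itself at 0.33 and -0.37. Among them Rpl13a was at -0.39, -1.70, 2.12 and 0.81 in these 4 comparisons, and the 3rd and 4th took the other sign with the local background subtracted (-0.87 and -1.92).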
